A study of Homo sapiens with 2 samples.

How the data were processed

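The series compared gene expression in HCT116, an established human colorectal cancer cell line, between 1 library labelled as an SRD5A1 knockdown and 1 library labelled as a control. The titles carry the tags "Dox" for the knockdown and "KD" for the control, and the labels do not say what either tag stands for. Groups were taken from the genotype given for each sample, and the columns of values were matched to the samples by the tags in the titles. There were no replicates, so no p-value, standard error or test between conditions was computed, and every difference describes these 2 libraries.

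Per the labels' protocols, total RNA was extracted with Trizol, poly(A) RNA was isolated with poly-T beads, fragmented and reverse-transcribed, and the libraries were sequenced as paired ends on an Illumina instrument. The protocol text speaks of an adipose type, which does not match a colorectal cancer line. Per the submitters' processing notes, Bowtie 0.12.2, HISAT2 2.0 and StringTie 1.3.0 were used, with no role or order given. The same notes name the build mm8, a mouse build. The deposited table holds human Ensembl identifiers, and of 31659 rows whose identifier is in GENCODE release 29 (GRCh38), 21949 (69.3%) have the same chromosome, start, end and strand there, so positions are given on GRCh38. The counting program, whether reads or fragments were counted, and the use of strand are not given in the sources used here.

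The authors deposited 1 table of 31798 rows with FPKM values (fragments per kilobase of transcript, scaled to the library total) and raw counts for each library. The deposited counts are whole numbers that sum to 54740670 in the knockdown and 41814981 in the control library. The 2 units share their library scaling. Over 8914 genes with at least 200 counts in both libraries, the library ratio of counts per FPKM had a median of 1.31 (5th to 95th percentile over genes 1.30 to 1.31), and the ratio of the total counts was 1.31. The design fixed before the data were examined assumed FPKM alone. FPKM therefore stayed the main measure, and the counts were used for depth, for counting intervals and for alternatives chosen after seeing the data.

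Rows were summed by gene symbol, which gave 28615 symbols, of which 1802 were on more than 1 row (4985 rows). Some symbols in the table are clone names without a version, so different genes can share one and be summed. The main measure was the difference in log2(FPKM + 1), knockdown minus control. A pseudocount of 1 understates the difference of weakly expressed genes. A gene counted as expressed at a mean FPKM of at least 1 over both libraries, which 10143 symbols reached, and as 2-fold apart at a difference of at least 1 on this scale. Ratios of CPM (counts scaled to 1000000 per library) carry exact Clopper-Pearson 95% intervals. Intervals of these ratios and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Intervals of medians are taken over genes or rows as if these were independent, and cover no spread between cultures or scalings. A count of 0 allows up to 3 counts, or 0.0548 CPM in the knockdown and 0.0717 in the control library.

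In the same design, 40 gene lists were fixed, with a rule for the genes to be named. The rule takes SRD5A1, SRD5A2 and SRD5A3, the 12 genes with the largest differences in each direction among named symbols with a mean FPKM of at least 5 and a value above 0 in both libraries, up to 4 members of each list with the largest differences at a mean FPKM of at least 5 (with at least 1 going against the list's median where one does), VEGFA, RELA, NFKB1 and NFKBIA, and at most 5 genes listed at 0 in one library and at 5 FPKM or more in the other. Some genes that the rule takes are not reported here. For each list with at least 5 expressed members, the median difference was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. A list stood apart below percentile 2.5 or above percentile 97.5, which chance gives for 5% of lists of unrelated genes. Members were counted as higher at a difference of 0.5 or more, as lower at -0.5 or less, and as between otherwise.

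The steps were tested on simulated data for the knockdown against control comparison, over 10171 genes with counts drawn at the real depths and a spread of 0.5 (log2 SD) added per gene. Of 200 genes changed 4-fold, 86.5% were found 2-fold apart in the right direction, against 2.16% of unchanged genes. A planted list of 20 genes shifted by 0.5 reached percentile 99.99, and 6% of 200 unshifted lists fell outside the limits. The added spread was independent between genes and the unshifted lists were random, so this rate does not cover lists whose members vary together. The observed differences spread more widely, with 25th and 75th percentiles of -0.24 and 0.87 over expressed genes. How much of that spread is noise is unknown, so the simulated rates may be too favourable for these libraries.

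The alternatives fixed before the data were examined were pseudocounts of 0.1 and 5, no filter on low values or a mean FPKM of at least 5, rescaling to a sum of 1000000, to a median ratio of 1 or to the upper quartile, leaving out mitochondrially encoded and ribosomal protein genes, keeping 1 row per symbol, and thresholds of 1.5-fold and 4-fold. Alternatives chosen after seeing the data were CPM, TMM scaling of the counts with edgeR 4.0.16, removal of the trend with GC content and transcript length (known for 10132, or 99.9%, of the expressed symbols), and protein-coding genes alone. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3.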

Results

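The transcriptomes of 2 HCT116 cultures were compared, 1 labelled as a knockdown of SRD5A1 and 1 labelled as a control. SRD5A1 encodes steroid 5-alpha reductase type 1, which reduces testosterone and other steroids at the 4,5 double bond. The question the design poses is which transcripts differ between the libraries when SRD5A1 is lowered. The knockdown library held 54740670 counts over 21792 genes with a count, and the control library 41814981 over 21981. There were no replicates, so differences are given as higher or lower in the knockdown library, and the spread between cultures is unknown. Intervals are counting intervals for single genes and intervals over genes for medians. The libraries differed in composition. Mitochondrially encoded genes took 12.8% of the counts in the knockdown and 18.3% in the control library, and the 10 most abundant genes took 11.3% and 19.8%.

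SRD5A1 (ENSG00000145545, GRCh38 chromosome 5, 6633427 to 6668972, plus strand, a protein-coding gene with 4 annotated transcripts and 5 exons in its principal transcript) was lower in the knockdown library. Its level was 6.25 FPKM (3119 counts) against 10.8 FPKM (4101 counts) in the control. The ratio of CPM (counts scaled to the library total) was 0.581 (95% interval 0.554 to 0.609), and the log2(FPKM + 1) difference was -0.70. In this main measure SRD5A1 was short of the 2-fold threshold, which 2808 of the 10143 expressed genes passed. Its level alone therefore does not establish the knockdown. The size of the difference depended on scaling, and it was -1.13 with the upper quartile and -0.44 with the GC and length trend removed (the SRD5A1 level is lower in the knockdown library in both). SRD5A2, the type 2 enzyme, had 0 counts in both libraries. SRD5A3, which acts in the synthesis of dolichol for N-glycosylation, was higher in the knockdown library, at 2.53 against 0.784 FPKM, with a CPM ratio of 3.22 (2.72 to 3.84). Its difference in the main measure, 0.98, was also short of the 2-fold threshold.

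Of the 10143 expressed genes, 2115 were at least 2-fold higher and 693 at least 2-fold lower in the knockdown library, so 75.3% of the 2808 genes 2-fold apart were higher. The median difference over all expressed genes was 0.30 (95% interval of the median 0.28 to 0.32) and was not subtracted: the differences and counts of members are relative to 0, while the percentiles of lists compare them with other genes of these libraries. The 5th and 95th percentiles over genes were -1.21 and 1.82. Across genes, which are not independent replicates, the libraries' values had a Spearman rho of 0.770. The split depended on scaling. With the median ratio set to 1 it was 1247 higher and 1109 lower (52.9% higher), with TMM 1542 and 980 (61.1%), and with the upper quartile 1032 and 1321 (43.9%).

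**Figure D1:**
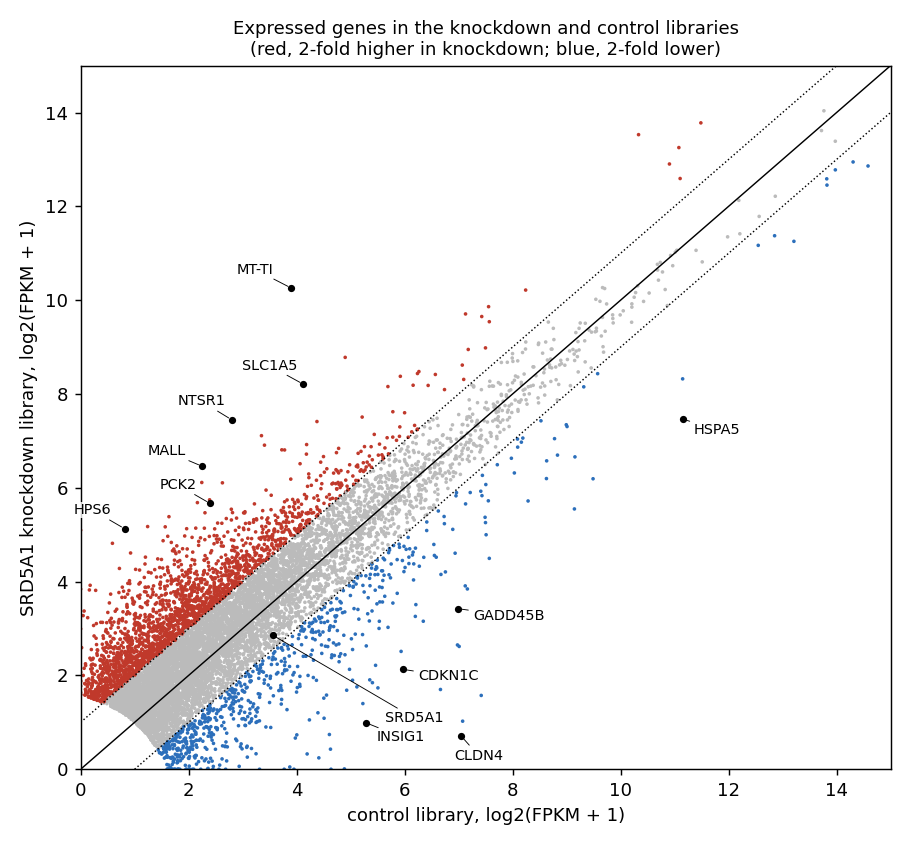
Each dot is 1 of the 10143 expressed genes, with its level in the control library on the x axis and in the SRD5A1 knockdown library on the y axis, both as log2(FPKM + 1). The solid line marks equal levels and the dotted lines a 2-fold difference, and 2115 genes (red) lie above and 693 (blue) below the dotted lines.

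The largest differences towards the knockdown library included a receptor and an amino acid transporter. NTSR1, the receptor for neurotensin (chromosome 20, 62708836 to 62762771), was at 174 against 5.96 FPKM, a difference of 4.65. SLC1A5, a glutamine and neutral amino acid transporter (chromosome 19, 46774883 to 46788594), was at 295 against 16.4 FPKM, a difference of 4.09. The others were MT-TI (6.36), HPS6 (4.31), MALL (4.21), CCDC71 (3.93), MT-TG (3.88), CENPB (3.87), MT-TW (3.76), RRS1 (3.75), HOXA10-AS (3.75) and METTL7B (3.69). MT-TI, MT-TG and MT-TW are short mitochondrial transfer RNAs that lie next to mitochondrial mRNAs of the same strand. Reads of these neighbours can reach into them, so their values are uncertain. HOXA10-AS overlaps other HOXA transcripts, so without stated strand use its value is uncertain too. Expressed protein-coding genes with 1 exon (124, histone genes left out) were higher as a class, 58.9% of them at least 2-fold. Neither the ranking nor the percentiles of lists, which match on expression alone, take this into account.

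The largest difference towards the control library was that of CLDN4, a tight junction protein (chromosome 7, 73799542 to 73832684), at 0.628 against 132 FPKM, a difference of -6.35. INSIG1, a sterol-regulated inhibitor of SREBP processing (chromosome 7, 155297776 to 155310233), was at 0.985 against 38.1 FPKM (-4.30). HSPA5, the endoplasmic reticulum chaperone BiP (chromosome 9, 125234853 to 125241343), was at 175 against 2288 FPKM (-3.70). The stress-inducible genes GADD45G (-4.20) and GADD45B (-3.57) and the cyclin-dependent kinase inhibitor CDKN1C (-3.85) were also among them, with the histone genes HIST2H2AA3 (-4.39), HIST2H2AA4 (-4.33) and HIST2H2BE (-3.87), and TENT5B (-3.77), MTCO1P12 (-3.60) and CPA4 (-3.56). HIST2H2AA3 and HIST2H2AA4 are near-identical copies, and MTCO1P12 is a nuclear copy of MT-CO1, so reads can be split between them.

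At 0 in one library and at 5 FPKM or more in the other were 5 genes absent from the knockdown library's counts and 3 absent from the control's. Of the 5 with the highest FPKM, INO80B-WBP1 was at least 643-fold and AC138811 at least 397-fold higher in the control library against the floor of 3 counts. AL691442 and RPL36A-HNRNPH2 were at least 287-fold and 136-fold higher in the control library, and RPL17-C18orf32 was at least 339-fold higher in the knockdown library. INO80B-WBP1, RPL17-C18orf32 and RPL36A-HNRNPH2 are readthrough genes that overlap their neighbours, so the assignment of reads may affect their values, which was not tested.

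Of the 40 gene lists, 35 had enough expressed members for a percentile, and 13 stood apart from expression-matched random lists (6 high and 7 low), against 1.75 by chance for lists of unrelated genes. The lists high in the knockdown library were G1/S and DNA replication, integrated stress response, ribosome biogenesis and MYC targets, Wnt/beta-catenin targets, NRF2 and oxidative stress, and drug efflux and xenobiotic metabolism. Of 25 expressed genes of G1/S and DNA replication, 23 were higher and 0 lower, with a median of 1.58 (percentile 100). The replicative helicase subunits MCM5 (22.3 against 2.90 FPKM, 2.58) and MCM2 (38.8 against 5.93, 2.52) and the transcription factor E2F1 (14.9 against 1.79, 2.51) led it, while the cyclin CCND3 was at -0.12. For the G2/M and mitosis genes, 9 of 19 were higher and 1 lower, and the median of 0.47 (percentile 73.4) did not stand apart and turned sign with the scaling (-0.01 to 0.61). PLK1 was at 1.34, FOXM1 at 10.4 against 3.79 FPKM, BIRC5 at 0.87 and CDC20 at -0.55.

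Of 20 integrated stress response genes, 14 were higher and 4 lower, with a median of 1.245 (percentile 100). The highest were PCK2, the mitochondrial enzyme that makes phosphoenolpyruvate (49.9 against 4.25 FPKM, 3.28), and PSAT1, an enzyme of serine synthesis (111 against 12.7, 3.03). The stress transcription factors DDIT3 (21.6 against 189 FPKM, -3.07) and ATF3 (7.14 against 50.7, -2.67) went the other way. Of 22 genes of ribosome biogenesis and MYC targets, 16 were higher and 0 lower, with a median of 1.07 (percentile 99.99), led by the nucleolar protein NOP56 (a CPM ratio of 4.32), ODC1, the first enzyme of polyamine synthesis (1.84), and the pseudouridine synthase DKC1 (1.77), with NOLC1 at -0.24. The Wnt/beta-catenin targets had 10 of 14 members higher and 4 lower, with a median of 0.90 (percentile 98.3). RNF43 (2.94), CCND1 (1.79) and SOX4 (1.46) were higher, and DKK1, a secreted Wnt inhibitor, was lower (-2.99).

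The NRF2 and oxidative stress list had 11 of 17 members higher and 2 lower, with a median of 0.66 (percentile 98.2). ABCC2 (1.92), NQO1 (1.55) and GSR (0.93) were higher, while FTL, the ferritin light chain, was at 2444 against 9481 FPKM (-1.96). The list was no longer apart in CPM (percentile 96.8) or with the GC and length trend removed (94.0). The drug efflux and xenobiotic metabolism list had 6 of 8 members higher and 0 lower, with a median of 1.003 (percentile 97.6), and it stood apart in 2 of 12 alternatives. ABCC3 (1.29), ALDH1A3 (1.16) and ABCC1 (1.14) were among them. Removing the GC and length trend also moved the Wnt list inside the limits (94.6).

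The lists low in the knockdown library were led by histones and sterol synthesis. All 9 expressed replication-dependent histone genes were lower, with a median of -2.83 (percentile 0), including HIST1H1C (-3.21) and HIST1H2BD (-2.85). Replication-dependent histone mRNAs mostly end without a poly(A) tail, as do small nucleolar RNAs and their relatives. The median was -1.62 over 48 expressed SNORD rows (40 lower), -0.99 over 33 SNORA rows (23 lower, 10 higher) and 0.16 over 6 SCARNA rows (2 lower, 4 higher). Of 23 expressed genes of cholesterol and sterol synthesis, 15 were lower and 3 higher, with a median of -0.86 (percentile 0), although the Gene Ontology term cholesterol biosynthetic process lay inside the limits (percentile 3.30). Besides INSIG1, the methylsterol oxidase MSMO1 (3.64 against 43.1 FPKM, -3.25) was lower, and TM7SF2, a sterol reductase, was higher (1.74). The fatty acid synthesis list did not stand apart (13 genes, median 0.02, percentile 20.2; -0.47 to 0.14 over the scalings), with ACLY at 1.06, ACSS2 at 0.88, ELOVL5 at -0.85 and SCD at -0.63.

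Of 17 genes of the unfolded protein response and ER chaperones, 8 were lower and 1 higher, with a median of -0.48 (percentile 0.17), although the Gene Ontology term endoplasmic reticulum unfolded protein response did not go with it (median 0.61, percentile 84.8). HERPUD1 (-2.13) and HSP90B1 (-1.77) were lower with HSPA5, and the transcription factor XBP1 was higher (1.10). At a mean FPKM of at least 5 the list no longer stood apart (percentile 19.8). The heat shock list had a median of -0.25 (12 genes, percentile 6.70) and stood apart with no filter on low values (percentile 1.88) and with the GC and length trend removed (2.23). HSPA1A (-2.57), HSPA1B (-2.50) and DNAJB1 (-2.43) were lower and HSPE1 (0.99) higher, and HSPA1A and HSPA1B are near-identical copies between which reads can be split. The autophagy and lysosome list had 7 of 21 members lower and 5 higher (median -0.19, percentile 1.60), with ATG12 (-2.23), MAP1LC3B (-1.71) and CTSB (-1.19) lower. With the median ratio set to 1 it fell within the limits (2.63).

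Of 19 p53 targets, 7 were lower and 5 higher (median -0.35, percentile 0.22). GADD45A (16.8 against 101 FPKM, -2.52), PLK3 (-1.71) and BBC3 (-1.34) were lower and XPC, a DNA repair factor, was higher (1.16). The list lost its place with no filter on low values (percentile 3.39) and with the GC and length trend removed (3.13). Of 12 mesenchymal and migration genes, 6 were lower and 3 higher (median -0.47, percentile 0.31), among them the repressor SNAI1 (-2.02) and CCN1 (-0.92), against S100A4 (2.31) and L1CAM (0.78). At a mean FPKM of at least 5 it was within the limits (percentile 3.65). Of 12 antigen presentation genes, 3 were lower and 4 higher (median -0.38, percentile 1.35). HLA-DRA (-1.45) and HLA-DRB1 (-1.36) were lower, and TAP2 (1.24) and PSMB9 (1.15) were higher.

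**Figure D2:**
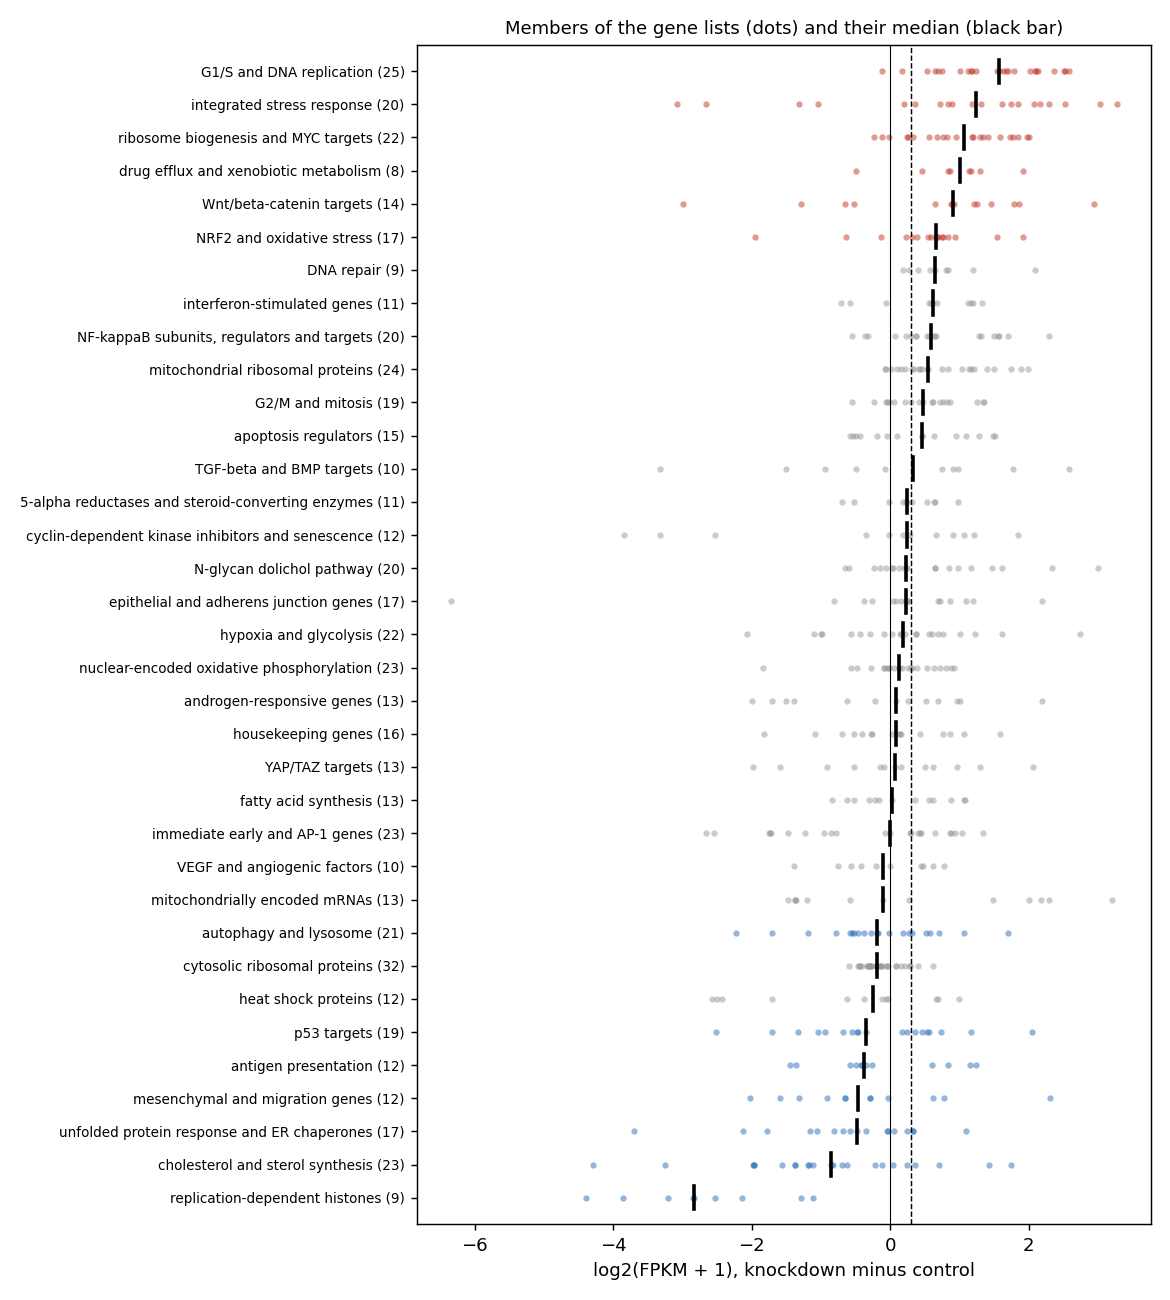
Each row is a gene list with its number of expressed members in brackets, dots are members, and the x axis is the log2(FPKM + 1) difference, knockdown minus control. Black bars are medians, the dashed line is the median of all expressed genes (0.30), and red and blue lists stood above or below expression-matched random lists, from a median of 1.58 for G1/S and DNA replication to -2.83 for replication-dependent histones.

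NF-kappaB and VEGF genes did not stand apart as lists, except that the VEGF list stood apart as low in 1 of 12 alternatives, with the GC and length trend removed. Of 20 NF-kappaB subunits, regulators and targets, 12 were higher and 1 lower, with a median of 0.59 (percentile 89.3). The subunit genes RELA and NFKB1 were at 0.56 and 1.57, the inhibitor NFKBIA at 1.31, TNFAIP2 at 1.56, PLAU at 38.7 against 13.1 FPKM and NFKB2 at -0.32. Of 10 VEGF and angiogenic factors, 2 were higher and 3 lower, with a median of -0.10 (percentile 6.5). VEGFA was at 4.15 against 2.72 FPKM (0.47; ratio 1.52, 1.44 to 1.61), VEGFB at 0.62, EFNA1 at 0.45 (-0.02 with the upper quartile), ANGPTL4 at -0.76 and EPHA2 at -0.57.

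Lists on steroid handling and the N-glycan dolichol pathway did not stand apart, and the sign of their medians turned with the scaling. The 11 expressed 5-alpha reductases and steroid-converting enzymes had a median of 0.24 (percentile 48.3; -0.09 to 0.40 over the scalings), with HSD17B10 at 0.63 and HSD17B8 at 0.23, whose sign turned with the median ratio set to 1, the upper quartile and TMM. The 13 androgen-responsive genes had a median of 0.08 (percentile 37.7; -0.37 to 0.20), with KRT18 at 2.20, CAMKK2 at 0.97, KRT8 at 0.69 and NDRG1 at -1.99. The 20 genes of the N-glycan dolichol pathway had a median of 0.23 (percentile 43.0; -0.20 to 0.37), with DOLK (12.9 against 0.736 FPKM), ALG1 (2.34) and ALG2 (1.16) higher and RPN2 lower (-0.65).

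Several other lists held strong differences both ways without standing apart in the main measure, and their medians also turned sign with the scaling. Hypoxia and glycolysis genes had a median of 0.19 (22 genes, percentile 59.7), with the glucose transporter SLC2A1 at 120 against 17.2 FPKM (2.74), SLC16A3 at 1.61, ALDOC at -2.07 and P4HA1 at -1.11. Cyclin-dependent kinase inhibitors and senescence genes had a median of 0.24 (12 genes, percentile 49.9), with CDKN2D (-2.52) and LMNB1 (1.85). TGF-beta and BMP targets had a median of 0.33 (10 genes, percentile 71.5), with the BMP target ID1 at 835 against 139 FPKM (2.58), ID3 at 1.77 and BAMBI at -0.94. Epithelial and adherens junction genes had a median of 0.23 (17 genes, percentile 64.7), with CLDN3 at 1.20 and the cadherin CDH1 at 0.86 beside the much lower CLDN4. Apoptosis regulators had a median of 0.45 (15 genes, percentile 72.4), with BIK (1.51), BCL2L1 (1.28), BAD (1.09) and BAK1 (-0.54). YAP/TAZ targets had a median of 0.07 (13 genes, percentile 21.2), with TEAD4 at 0.96. Immediate early and AP-1 genes had a median of -0.01 (23 genes, percentile 17.7), with the phosphatase DUSP1 at -2.55, KLF6 at -1.75 and DUSP6 at 1.35, and at a mean FPKM of at least 5 this list stood apart as low (percentile 0.14).

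Interferon-stimulated genes had a median of 0.62 (11 genes, percentile 83.3; 99.1 with no filter on low values), with OASL at 1.16, ISG15 at 0.68 and IRF7 at -0.72. DNA repair genes had a median of 0.64 (9 genes, percentile 85.0; 97.9 with no filter), with XRCC1 at 0.83 and PARP1 at 0.57. Mitochondrial ribosomal proteins had a median of 0.54 (24 genes, percentile 83.9; 98.2 at a mean FPKM of at least 5 and 97.7 with the GC and length trend removed), with MRPS18A (1.99), MRPL15 (1.90) and MRPL12 (1.75) higher. Cytosolic ribosomal proteins had a median of -0.20 (32 genes, percentile 16.1; 2.20 with no filter), with RPS3 at 0.61 and RPL8 at -0.60. The sign of the median turned with the scaling for nuclear-encoded oxidative phosphorylation (0.13, 23 genes, percentile 42.8, with COX7B at -1.84 and ATP5PD at 0.93), and for housekeeping genes (0.08, 16 genes, percentile 39.0, with TFRC at -1.09 and ACTB at 0.86). Only 3 colon differentiation genes were expressed, with a median of 0.10 that also turned sign.

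The 13 mitochondrially encoded mRNAs went both ways, although most of them come from 1 shared precursor transcript. MT-ND2 (11826 against 1289 FPKM, 3.20), MT-ATP6 (2.29), MT-ND1 (2.17), MT-ND3 (7665 against 1917 FPKM) and MT-CYB (1.49) were higher in the knockdown library. MT-ND5 (-1.48), MT-ND6 (-1.38), MT-ND4 (-1.37), MT-CO1 (-1.36) and MT-ND4L (-1.20) were lower. MT-CO3 was at -0.59, MT-CO2 at -0.10 and MT-ATP8 at 0.27. The list median of -0.10 (percentile 44.6) turned sign with the scaling. MT-ATP8 and MT-ATP6 overlap, as do MT-ND4L and MT-ND4, so reads can be shared within those pairs.

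**Figure D3:**
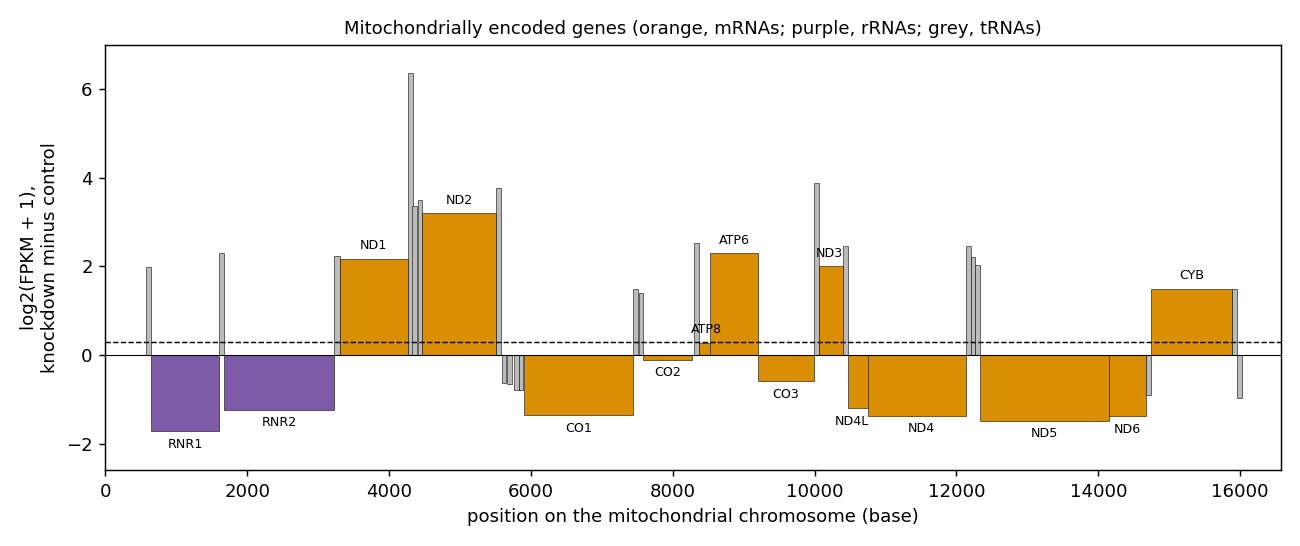
Bars are the mitochondrially encoded genes at their position on the mitochondrial chromosome (x axis, in bases), and their height is the log2(FPKM + 1) difference, knockdown minus control. Orange bars are the 13 mRNAs, 5 of them at least 2-fold higher and 5 at least 2-fold lower, purple bars are ribosomal RNAs, grey bars are transfer RNAs, and the dashed line is the median of all expressed genes (0.30).

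Markers of other cell types were few. COL1A1 was the 1 expressed fibroblast marker (2.39 against 4.02 FPKM), and 0 endothelial markers were expressed. Of the blood and immune markers, CD68 (1.28 against 7.79 FPKM), HBA1 (0.913 against 7.25) and HBA2 (0.704 against 5.52) were expressed, all lower in the knockdown library, and HBA1 and HBA2 are near-identical copies. Of the adipocyte markers, PPARG (5.997 against 2.23 FPKM) and CFD (57.0 against 16.7) were expressed, both higher in the knockdown library. PPARG is also expressed in colon epithelium.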

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

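TMM, CPM, the removal of the GC content and length trend and the restriction to protein-coding genes were chosen after seeing the data. No paired analysis was possible because each group has 1 library, and for the same reason leaving out a column in turn was not run. The SRD5A1 level was lower in the knockdown library under every alternative run, with differences of -0.77 (pseudocount 0.1), -0.49 (pseudocount 5), -1.02 (median ratio set to 1), -1.13 (upper quartile), -0.80 (mitochondrial and ribosomal protein genes left out), -0.77 (CPM), -0.93 (TMM) and -0.44 (GC and length trend removed). The genes at least 2-fold apart, higher in knockdown and lower in knockdown, numbered 730 and 278 with a pseudocount of 5, 1136 and 345 at a mean FPKM of at least 5, 1247 and 1109 with the median ratio set to 1, 1032 and 1321 with the upper quartile, 3758 and 1422 at 1.5-fold, and 358 and 149 at 4-fold. A smaller tested set or another threshold gives part of these by construction, and the cause of the rest was not tested. The median log2 difference over all expressed genes was 0.37 (pseudocount 0.1), 0.17 (pseudocount 5), 0 (no filter on low values), 0.32 (mean FPKM of at least 5), 0.45 (rescaled to 1000000), 0.34 (mitochondrial and ribosomal protein genes left out), 0.35 (CPM), 0.10 (TMM) and 0.36 (protein-coding genes). It was -0.0014 with the median ratio set to 1, by construction, and turned to -0.11 with the upper quartile. Of 1873 values of named genes under alternatives, 853 stayed within their counting interval and 1020 moved. The sign turned in 14 of them, in 6 genes (HSD17B8, CA2, XRCC5, XRCC6, EFNA1 and MRPL22), and in 0 values of the 24 genes with the largest differences. Those 24 were picked for differences far above the shifts between scalings, so their signs could hardly turn. Of 418 list medians, 391 stayed within their interval and 27 moved. The sign turned in 37 of them, in 15 lists, and in 0 medians of the lists apart. Of the lists not apart, 7 stood apart in at least 1 alternative. Among the lists apart, histones, sterol synthesis, G1/S, integrated stress response, ribosome biogenesis and antigen presentation stayed apart in all 12 alternatives. The alternatives that only rescale the libraries shift a list and its random lists alike, so they change percentiles little.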

Other observations

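A screen of 930 Gene Ontology terms with 15 to 150 expressed members, made after seeing the data and with 2000 random lists per term, put 48 terms above and 60 below the limits, against 46.5 by chance, so that a large part of the terms outside the limits is what chance alone gives. Amino acid transport was high in the knockdown library, with a median of 1.23 over 26 genes, 15 of them at least 2-fold higher and 0 lower. Beside SLC1A5 it held SLC38A10 (3.52) and both chains of the large neutral amino acid transporter, SLC7A5 (341 against 94.0 FPKM, 1.85) and SLC3A2 (117 against 37.3 FPKM, 1.62). The tRNA methylation genes had a median of 1.10 over 15 genes, with 9 at least 2-fold higher, among them the methyltransferases METTL1 (18.1 against 1.59 FPKM, 2.88) and NSUN2 (1.80). Genes of COPII-coated vesicles, which carry cargo from the endoplasmic reticulum to the Golgi, had a median of -0.39 over 27 genes (percentile 0), with 5 at least 2-fold lower, among them TMED7 (-1.83) and LMAN1 (-1.44), and 3 at least 2-fold higher. The related term of COPII vesicle coating had a median of 0.06 over 43 genes and lay inside the limits (percentile 3.95).

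Terms of the same screen that resemble fixed lists did not all go with them. Wnt signaling pathway (72 genes, percentile 61.15) and response to oxidative stress (55 genes, percentile 86) lay inside the limits. So did antigen processing and presentation of exogenous peptide antigen via MHC class II (48 genes, percentile 18.45). Against the low p53 list, regulation of signal transduction by p53 class mediator (56 genes, percentile 58.4) lay inside the limits. Against the low mesenchymal and migration list, so did cell migration (62 genes, percentile 50.35). Against the high ribosome biogenesis list, ribosomal small subunit biogenesis (16 genes, percentile 15.7) and ribosomal large subunit assembly (21 genes, percentile 64.6) did as well. Other related terms are not listed here. The term autophagy (82 genes, percentile 0.75) was below the limits, as was the autophagy and lysosome list. Against the low list of cholesterol and sterol synthesis, the terms sterol biosynthetic process (17 genes, median -0.62, percentile 0), cholesterol homeostasis (median -0.24, percentile 1.35) and cholesterol metabolic process (median -0.04, percentile 1.5) were below the limits, while cholesterol biosynthetic process (22 genes, median -0.07, percentile 3.30) and steroid biosynthetic process (median 0.01, percentile 4.65) lay inside the limits. Against the low list of the unfolded protein response and ER chaperones, the terms IRE1-mediated unfolded protein response (40 genes, median -0.09, percentile 0.6) and response to endoplasmic reticulum stress (31 genes, median -0.10, percentile 1.4) were below the limits. The terms endoplasmic reticulum unfolded protein response (18 genes, median 0.61, percentile 84.8, 6 at least 2-fold higher and 1 lower) and response to unfolded protein (31 genes, median 0.38, percentile 61.05) lay inside the limits, with medians above 0.

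MYC, chosen after its values were seen, had 6307 counts in the knockdown and 2519 in the control library, a difference of 0.88.

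For the surplus of genes higher in the knockdown library, the tests of counting noise, scaling, GC content and silent genes were chosen after the result was seen, and the test of single-exon genes was set before. At most 6 genes were 2-fold apart in 100 simulated pairs with counting noise alone, which argues against counting noise. Scaling to library totals and a trend with GC content and length stay open, because setting the median to 0 itself pulls the ratio of higher to lower genes towards 1 (it was 1.12), and removing the trend keeps the overall median and so the surplus (the number of 2-fold genes was 93.0% of that before). Genomic DNA was first to be judged by the 124 expressed protein-coding genes with 1 exon, with histone genes left out. Their median of 1.22 lay 0.93 above matched lists, past the 0.5 set in advance as the sign of genomic DNA (0.89 after the GC and length trend was removed). A test chosen after that value then argued against it, because DNA would cover silent genes too, and the 234 single-exon genes under 0.1 FPKM in the control library gained 0.0224 FPKM at the 75th percentile against a median gain of 4.32 FPKM of the expressed ones. The median was 0.77 at 2 exons and 0.49 at 3, lay between 0.34 and 0.37 from 4 to 20 exons and was 0.28 at 21 or more, and what sets the higher values at few exons stays open, as do the knockdown, the treatment behind the tags and any difference between cultures or preparations.

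For the mitochondrially encoded mRNAs, the test of nuclear copies and the comparison with 1 common factor were chosen after the result was seen. With the counts of named nuclear copies added, 10 of the 13 mRNAs stayed at least 2-fold apart, which argues against reads shared with those copies. A different content of mitochondrial RNA as a whole would move them by 1 factor, which alone cannot give differences both ways. Their log2 ratios spanned 4.68, but a wide span follows from mRNAs 2-fold apart both ways, so this value restates the pattern. Processing or stability of single transcripts and differences in library preparation stay open, and no biological explanation was tested.

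For the lower histone and small nucleolar RNA levels in the knockdown library, the test was set before its result was seen. Carry-over of RNA without a poly(A) tail into the control library would leave other such RNAs, those not released from introns, lower in the knockdown library too. The median over 29 of them was -1.14 (95% interval -1.37 to -0.66), with 26 lower, while RN7SL1 (-0.25) and RN7SL2 (0.05) stayed near 0. All 29 rows together held only 1076 counts in the knockdown and 1743 in the control library, so this median rests on few counts. All 27 expressed histone rows were lower, with a median of -1.85 (-2.53 to -1.57). Host genes of small nucleolar RNAs (SNHG rows), whose spliced transcripts carry a tail, had a median of -0.59 over 18 rows (-1.02 to 0.05), with 13 lower, which carry-over does not predict, so the small nucleolar RNA part of the pattern stays open. For the histones, the median of -1.14 went the way that carry-over predicts. On so few counts, a different yield of poly(A) selection is neither shown nor excluded as part of the histone difference. The gene counts also do not tell histone transcripts with a tail from those without one.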
